A study of Aspergillus fumigatus with 12 samples.

How the data were processed

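RNA sequencing was analysed in 12 libraries of Aspergillus fumigatus, a filamentous fungus that infects the human lung. The strain was CEA17, an akuB knock-out; akuB encodes a protein of non-homologous end joining, and its loss eases gene targeting. Per the labels' protocols, spores were grown for 16 h in minimal medium with glucose at 37 °C and 200 rpm, the compounds were then added, and treated cultures were collected 4 h later. Total RNA was extracted with a column kit, libraries followed a standard Illumina procedure and reads were 50 bp single-end, per the labels' protocols. Whether poly(A) RNA was selected or ribosomal RNA removed, and whether strand was kept, is not given in the sources used here. The 4 groups of 3 libraries were untreated (0 h), caspofungin (0.1 mg/L, 4 h), siamycin (1 mg/L, 4 h) and the combination of both at those doses (4 h). The series title names the lasso peptide humidimycin whereas the sample labels name siamycin, and the labels do not say whether these are one compound; the labels' name is used here. The series' design text mentions 4 time points, and the labels hold 2 (0 and 4 h). Replicates carry the letters a, b and c. Nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

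The deposited table held a normalised read signal for 10160 features per library. The submitters' processing notes name TopHat 1.4.1 and DESeq with no role; the genome build, annotation and counting tool are not given in the sources used here. In each library, every deposited signal value was a whole multiple of the smallest one: 100% of values lay within 0.01 of a whole number of reads, and the largest distance was 0.000956. The deposited signal is thus a read count divided by 1 factor per library, and whole reads could be recovered. The features were 10109 tags with the prefix AFUB_, 35 identifiers with the prefix CADAFUBT and 16 named non-coding RNAs. Reads of paralogs, overlapping genes and antisense genes may have been split or merged by the counting, which makes such genes uncertain. The reference gene table used here belongs to another strain with other tags: 0 identifiers matched, and neither the table nor the deposited file pairs the AFUB_ tags with names. The 25 gene lists by identifier (185 identifiers) and 21 lists by product keyword fixed before the data were examined therefore had 0 members matched, their tests were not run, and neither akuB nor any other gene could be followed by name.

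Recovered depth was 40083466 to 80586547 reads per untreated library, 5706401 to 9099970 with caspofungin, 7584848 to 14221298 with siamycin and 4839307 to 6199735 with the combination. Depth and treatment were therefore not independent. Shares of reads are given with their spread over libraries; floors of 3 reads cover counting error only.

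The tests fixed before the data were examined assumed raw counts. Because the deposited values were normalised, the test used was limma 3.58.1 in R 4.3.3 on log2(value + 4), with an intensity trend, robust moderation and 1 weight per group, over all 12 libraries in 1 model with 4 groups. Features with a value of at least 35 in at least 3 libraries were tested (8079 features, of which 8072 were AFUB_ tags); in the shallowest library this value equals 10.1 reads. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison, and fold changes are on the log2(value + 4) scale, which understates the change of low genes. The pseudocount, filter and weighting were set after the data had been seen. In particular, 3 weightings were run on these libraries in turn before 1 was kept: none, 1 per library and 1 per group, which called 959, 630 and 451 genes between combination and caspofungin. The choice rested on simulations and on the weights themselves, because weighting per library gave 1 untreated library a weight of 30.6. In data simulated from these libraries, 200 of 8079 genes were changed in each of 5 simulations. Without weights, false calls made up 11.4% of calls for combination versus caspofungin and 9.03% for combination versus siamycin; with 1 weight per group these shares were 5.02% and 5.41%. The group weights were not better throughout: for siamycin versus untreated the false share was 7.91% with them and 3.50% without, and for caspofungin versus untreated 5.54% and 3.81%. These simulations gave each gene the same spread beyond counting noise in all groups, although group weights model groups that differ in spread. Most real comparisons also called far more than 200 genes, so the false shares may not hold for them. With group weights, 1.5-fold changes were recovered in 50.8% (combination versus caspofungin) to 74.6% (siamycin versus untreated) of cases, and 2-fold changes in 89.2% to 94.3% for these comparisons.

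The data gave 6 pairwise comparisons. The 3 comparisons with untreated libraries hold 4 h of further culture as well as the treatment, since all untreated libraries were taken at 0 h; the 3 comparisons among treated groups were matched in time. A seventh contrast, the caspofungin effect with siamycin minus that without, also holds the culture time with a minus sign and is not read as an interaction. Replicate pairs of a group differed beyond counting noise, with chi-square per degree of freedom from 3.48 to 109.5, so that no library was counted as a duplicate. Correlations across genes are descriptions, because genes are not independent replicates.

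The rule for named genes, fixed beforehand, took called genes with the largest rises and falls among genes with a mean log2 CPM of at least 4 and no overlap between the replicates of both groups. Its requirement of an annotated product could not be applied, its part on genes known by name did not apply, and it was limited to 2 rises and 2 falls per comparison, since the tags carry no names. The named non-coding RNAs among tested features, the identifier CADAFUBT00010141 and runs of consecutive tags were added after their values were seen.

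Alternatives fixed before the data were examined were edgeR 4.0.16 quasi-likelihood tests on the recovered reads with DESeq2 size factors, library totals only or upper-quartile factors, and DESeq2 1.42.0. Others were limma-voom, no filter, a mean CPM of at least 10, only the groups compared, the replicate letter as a block, a fold change above 1.5 and leaving out each library in turn. Chosen after seeing the data were edgeR with TMM, pseudocounts of 1 and 16, other weights, reads thinned to equal depth (also without weights and with edgeR) and library totals without the ribosomal RNA rows. The recovered reads under edgeR with TMM gave 4495 calls for caspofungin versus untreated, 3934 for siamycin versus untreated, 4794 for combination versus untreated, 672 for combination versus caspofungin, 4712 for combination versus siamycin and 4837 for caspofungin versus siamycin.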

Results

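Transcript levels were measured by RNA sequencing in 12 libraries of Aspergillus fumigatus: 3 untreated, 3 exposed for 4 h to caspofungin, 3 to siamycin and 3 to both. Caspofungin is an echinocandin that inhibits synthesis of the cell wall polymer β-1,3-glucan; siamycin is the labels' name for the second compound, and the series title speaks of a lasso peptide, a threaded ring-and-tail peptide. The question named by the series title is whether such a peptide acts on the pathway by which fungi survive caspofungin. Normalised read counts were tested for 8079 features. The libraries separated by treatment: the first principal component held 73.2% of the variance and parted the 6 libraries with caspofungin (37.1 to 46.8) from the 6 without (-47.9 to -35.1), and the second, with 13.1%, parted untreated (-28.3 to -24.2) from siamycin libraries (21.5 to 25.3). Replicates within a group correlated at 0.984 to 0.996 across genes.

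Ribosomal RNA took a far larger share of reads wherever caspofungin was present. The 3 named ribosomal RNA rows and the unnamed feature CADAFUBT00010141, which followed them, took 42.3 ± 8.78% of reads with caspofungin (SD, n = 3) and 45.3 ± 3.85% with the combination. The named rows alone took 20.8 ± 4.37% and 23.3 ± 2.87%, against 0.442 ± 0.0557% in untreated and 0.591 ± 0.136% in siamycin libraries. With the unnamed feature the shares were 0.648 ± 0.0841% in untreated and 0.850 ± 0.153% in siamycin libraries (SD, n = 3 each). The 6 libraries with caspofungin (43.8 ± 6.28%) differed from the 6 without (0.749 ± 0.156%) in an exact two-sided permutation test (p = 0.002165). This is the smallest p that test can give, and the groups were pooled after the shares had been seen. It also treats libraries as independent, although replicates may be technical. Normalised reads of 18S ribosomal RNA, a part of the small ribosomal subunit, were 76.7-fold higher with caspofungin than untreated (log2 6.26 ± 0.22 SE). The row named 28S, from the large subunit, was 401-fold higher (log2 8.65 ± 0.42). The limma adjusted p values were 2.24e-12 and 7.55e-08. Whether poly(A) RNA was selected or ribosomal RNA removed is not given. Values of ribosomal RNA rows, here and below, therefore describe reads and not amounts in the cells. The 28S row was small, with 0.714 ± 0.244% as many reads as 18S in untreated libraries and 3.63 ± 0.17% with caspofungin (SD, n = 3 each). Reads outside these rows numbered 2990643 to 6173193 with caspofungin, 2625152 to 3281675 with the combination, 7512040 to 14091224 with siamycin and 39829131 to 80125653 in untreated libraries.

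**Figure D1:**
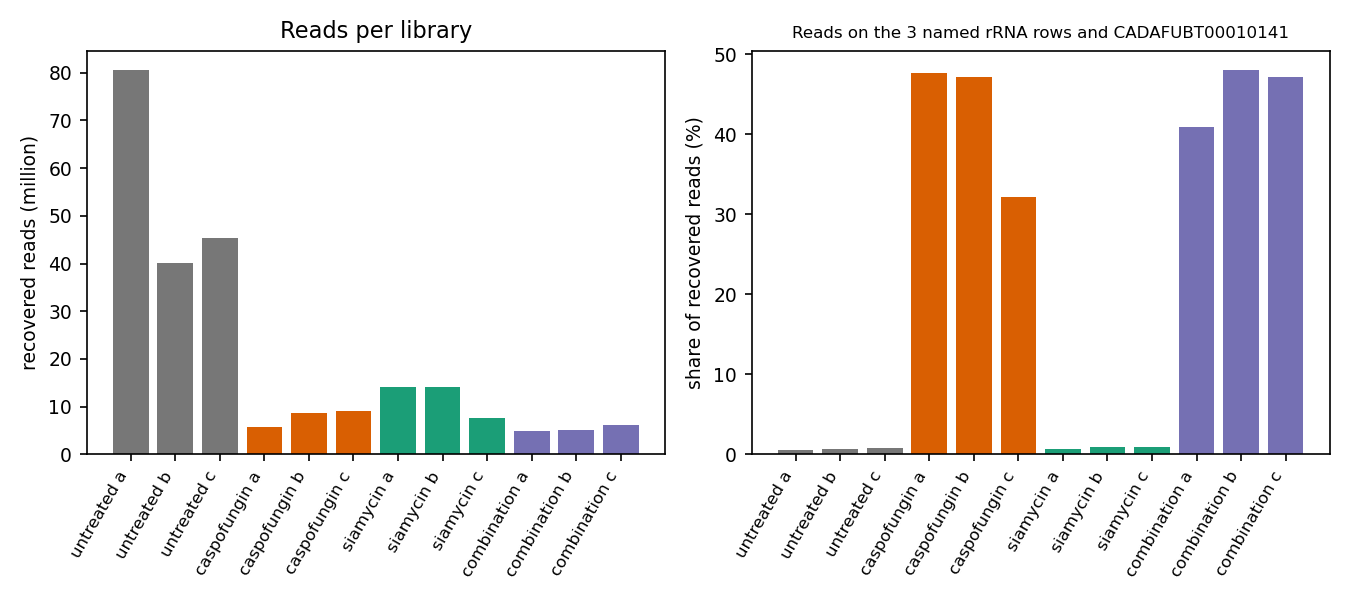
Recovered reads (left, 4839307 to 80586547) and the percent of them on the 3 named ribosomal RNA rows and CADAFUBT00010141 (right), 1 bar per library, coloured by group. The 6 libraries with caspofungin lie between 32.2% and 48.0% on the right, and the other 6 below 1%.

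Caspofungin for 4 h went with changes in 4217 of 8079 genes against untreated cultures at 0 h. Of these, 2012 rose and 2205 fell, and at least 2-fold changes were seen for 487 and 781. AFUB_051200 rose from 7.06 ± 1.70 to 5462 ± 1236 normalised reads (SD, n = 3 each; log2 8.94 ± 0.16 SE, adjusted p = 4.39e-16). AFUB_051170, a nearby tag, rose from 7.01 ± 1.69 to 2732 ± 910 (log2 7.92 ± 0.20, adjusted p = 6.91e-14). AFUB_030300 fell from 2205 ± 464 to 24.1 ± 5.71 (log2 -6.29 ± 0.18, adjusted p = 1.34e-13). AFUB_047540 was at 997 ± 117 in untreated libraries and had 0 reads with caspofungin, at least 513-fold lower against a floor of 3 reads over the group. Among non-coding RNAs, RNase_MRP, which takes part in ribosomal RNA processing, rose by 0.61 ± 0.19 (adjusted p = 0.0125) and had the opposite sign, -0.088, with scaling by library totals alone. Without caspofungin replicate b its value was 0.39 (adjusted p = 0.14), and at equal depth 0.48 (adjusted p = 0.523). SNORD14, a small nucleolar RNA, was at -0.62 ± 0.24 (adjusted p = 0.0436), a call that ended with limma-voom (0.0541), without weights (0.0644), at equal depth (-0.38, 0.38) and without untreated replicate b (0.105) or c (0.121) or caspofungin replicate a (0.115) or b (0.167). Scaling by library totals alone, which counts the ribosomal reads, shifted the median gene by -0.75 and left 6.46% of 7370 calls as rises, against 47.7% in the fit above; upper-quartile factors gave 51.5% rises among 4524 calls. The test was limma over all 12 libraries, and drug and 4 h of culture could not be separated.

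Siamycin for 4 h went with changes in 3911 genes against untreated cultures, and most changes were small. Rises numbered 2183 and falls 1728; at least 2-fold, 458 rose and 114 fell. AFUB_036280 rose from 7.63 ± 0.465 to 261 ± 128 normalised reads (SD, n = 3 each; log2 4.37 ± 0.34 SE, adjusted p = 2.5e-06). Its neighbour in tag order, AFUB_036270, rose from 9.17 ± 0.404 to 207 ± 68.2 (log2 3.95 ± 0.22, adjusted p = 7.78e-09). AFUB_081840 fell from 2789 ± 331 to 326 ± 149 (log2 -3.16 ± 0.35, adjusted p = 5.89e-05). AFUB_047540 again had 0 reads, at least 1225-fold below untreated. U3, the small nucleolar RNA that guides early cleavage of the ribosomal RNA precursor, fell from 1972 ± 140 to 852 ± 103 (log2 -1.21 ± 0.11, adjusted p = 3.62e-07). Smaller values, whose calls did not hold throughout, were those of 28S (log2 1.29 ± 0.36, adjusted p = 0.015), 18S (0.48 ± 0.19, adjusted p = 0.0489), U4, a spliceosomal RNA (-0.54 ± 0.21, adjusted p = 0.0398), and RNase_MRP (-0.48 ± 0.16, adjusted p = 0.0219). The 28S call ended without siamycin replicate b (adjusted p = 0.0633) or c (adjusted p = 0.0546). The 18S, U4 and RNase_MRP calls ended without weights (adjusted p = 0.11, 0.117 and 0.0738). The 18S call also ended with edgeR and TMM (adjusted p = 0.0857), DESeq2 (0.0624), limma-voom (0.108), the replicate block (0.0508) and without any 1 of 5 of the 6 libraries (0.0679 to 0.205; siamycin replicate a was the exception). The U4 call also ended with the block (0.0653), at equal depth (-1.03, 0.0608) and without untreated replicate b (0.0942) or c (0.133) or siamycin replicate b (0.125) or c (0.101). The RNase_MRP call also ended at equal depth (-0.52, 0.497) and without untreated replicate c (0.102) or siamycin replicate c (0.0803). Rises were 45.1% of calls with library totals alone and 48.1% with upper-quartile factors, against 55.8% here.

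The combination differed from untreated cultures in 4721 genes, and its extremes were those of caspofungin. Rises numbered 2287 and falls 2434, with 484 and 788 at least 2-fold. AFUB_051200 reached 4156 ± 325 normalised reads (SD, n = 3; log2 8.56 ± 0.17 SE, adjusted p = 7.55e-16) and AFUB_051170 reached 2302 ± 325 (log2 7.71 ± 0.20, adjusted p = 9e-14). AFUB_030300 fell to 27.0 ± 3.80 (log2 -6.14 ± 0.18, adjusted p = 2.48e-13), and AFUB_047540 had 0 reads, at least 310-fold below untreated. Both 18S (log2 6.59 ± 0.22) and 28S (8.79 ± 0.42) rose. U3 rose by 0.68 ± 0.13 (adjusted p = 0.000292) and RNase_MRP by 0.67 ± 0.19 (adjusted p = 0.00713); with library totals alone their values were -0.20 and -0.21, and at equal depth the RNase_MRP call ended although its value was 0.75 (adjusted p = 0.269). SNORD14 fell by 1.30 ± 0.25 (adjusted p = 0.000302). Library totals alone shifted the median gene by -0.92, and 5.08% of 7612 calls were then rises, against 48.4% here; upper-quartile factors gave 52.5% rises among 4779 calls.

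**Figure D2:**
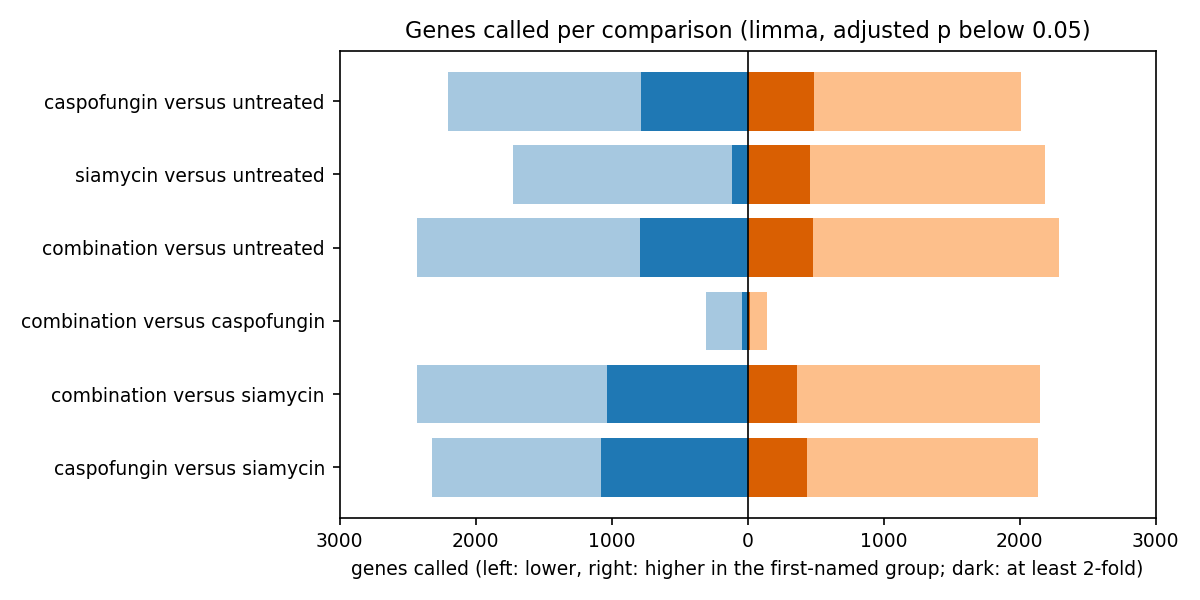
Number of genes called per pairwise comparison by limma at an adjusted p below 0.05, falls to the left and rises to the right of 0, with changes of at least 2-fold in dark colour. Combination versus caspofungin had 451 calls and the other 5 comparisons 3911 to 4721.

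Genes moving the same way in all 3 treated groups numbered 1218, of which 704 rose and 514 fell. Lists drawn independently would share 296 in this way, and unchanged groups simulated against the same untreated libraries shared 0 on average in 50 simulations; unchanged groups yield few calls, so this value does not measure how the shared libraries raise the overlap of changed lists. The figure of 296 is no reference either, because the caspofungin and combination groups shared the drug. Against untreated, 1651 genes rose and 1786 fell in both of these groups, and 19 moved in opposite directions. An excess over 296 was therefore fixed in advance. The 3 untreated libraries cannot be split into parts of at least 2, so part of the excess may also come from these shared libraries. Without untreated replicate c the overlap was 777, and with a required fold change above 1.5 in edgeR it was 173. Caspofungin and siamycin changed 2278 genes in both comparisons with untreated, of which 793 rose in both, 609 fell in both and 876 moved in opposite directions; independent lists would give 544, 472 and 1026. The covariance of both sets of fold changes was 0.0581, and simulated unchanged groups gave 0.00836; the correlation across genes was 0.111 against 0.379 simulated. For caspofungin and the combination the covariance was 0.820 (simulated 0.00849) and the correlation 0.940 (simulated 0.309). Fold changes of unchanged groups hold only noise, part of it from the shared libraries. Their correlations are therefore no reference for groups with real changes.

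Adding caspofungin to siamycin, a comparison matched at 4 h, changed 4585 genes, with 2151 rises and 2434 falls. At least 2-fold, 360 rose and 1031 fell. AFUB_051200 was at 13.5 ± 2.94 normalised reads with siamycin and 4156 ± 325 with both (SD, n = 3 each; log2 7.91 ± 0.17 SE, adjusted p = 2.69e-15). AFUB_046180 rose from 9.84 ± 3.30 to 2232 ± 98.6 (log2 7.36 ± 0.22, adjusted p = 8.61e-13). AFUB_084630 fell from 1188 ± 236 to 5.52 ± 2.30 (log2 -6.98 ± 0.25, adjusted p = 1.43e-12), and AFUB_030300 fell from 2991 ± 312 to 27.0 ± 3.80 (log2 -6.60 ± 0.19, adjusted p = 2.38e-13). The non-coding RNAs 18S (log2 6.11 ± 0.23), 28S (7.50 ± 0.44), U3 (1.89 ± 0.13), RNase_MRP (1.15 ± 0.20) and U4 (0.96 ± 0.25) rose, and SNORD14 fell by 0.91 ± 0.26. With library totals alone U4 was at 0.32 (adjusted p = 0.34) and RNase_MRP at 0.37 (adjusted p = 0.12); the RNase_MRP call also ended at equal depth, at 1.26 (adjusted p = 0.0658), and that of SNORD14 without combination replicate a (-0.60, adjusted p = 0.0566). Library totals alone shifted the median gene by -0.82, and 4.22% of 7233 calls were then rises, against 46.9% here. Upper-quartile factors turned the majority to rises, with 2782 rises and 2198 falls (55.9%).

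Most genes called for caspofungin both with and without siamycin moved in the same direction (94.5% of 2985). Fold changes of caspofungin versus untreated and combination versus siamycin, which share no library, correlated across genes at 0.81 (jackknife SE 0.0104 over libraries; Spearman 0.708). In both comparisons 1247 genes rose and 1573 fell, against 536 and 664 for independent lists, and 165 moved in opposite directions against 1193. Unchanged groups simulated 50 times gave a mean correlation of 0.00436 and a highest of 0.041. Genes were simulated independently of each other, so values near 0 were fixed in advance and do not give the chance range of real libraries. In 100 random regroupings of the libraries it ranged from -0.915 to 0.908, and 8 were as high or higher; these mix libraries with and without caspofungin and are no reference for unchanged groups.

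**Figure D3:**
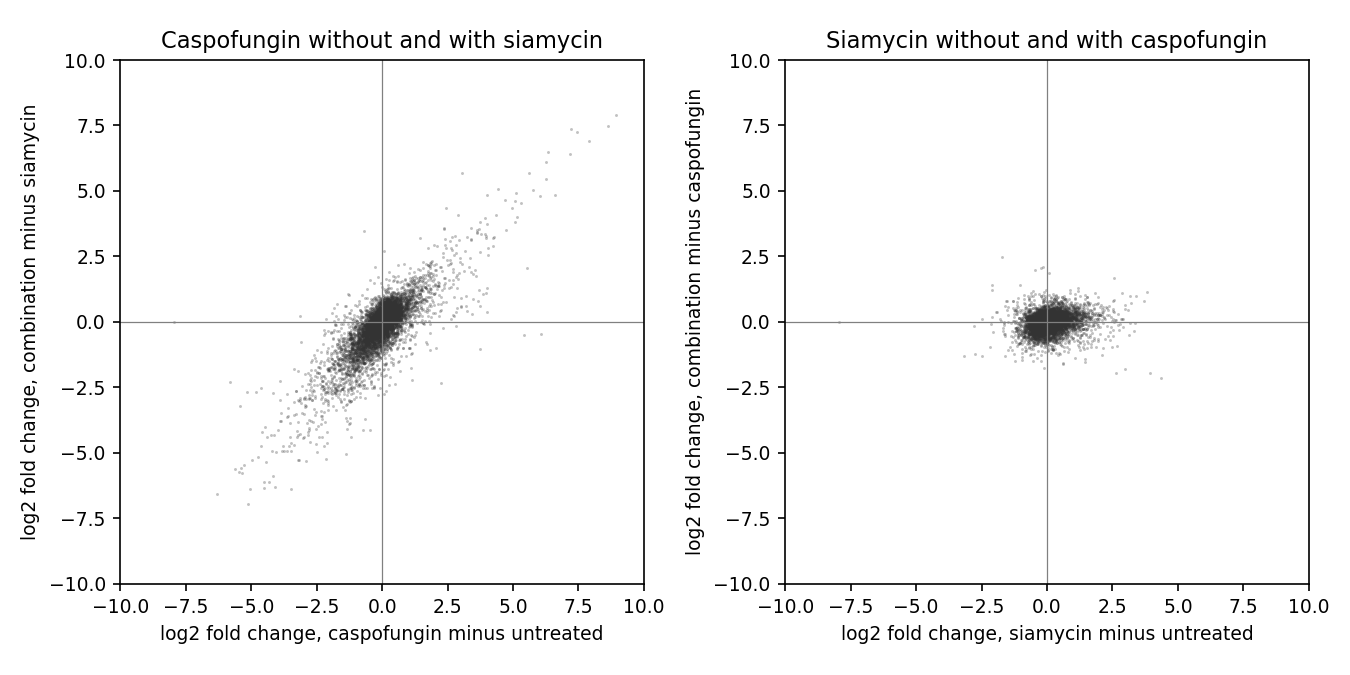
Log2 fold changes of 8079 genes, 1 point per gene, for caspofungin without (x) and with siamycin (y) on the left, and for siamycin without (x) and with caspofungin (y) on the right. The points follow the diagonal on the left (r = 0.81) and hardly do so on the right (r = 0.15).

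Adding siamycin to caspofungin, also matched at 4 h, changed 451 genes, of which 144 rose and 307 fell. At least 2-fold, 18 rose and 43 fell. AFUB_091070 rose from 169 ± 35.8 to 1006 ± 400 normalised reads (SD, n = 3 each; log2 2.48 ± 0.35 SE, adjusted p = 0.00258), and AFUB_048310 from 114 ± 35.02 to 515 ± 191 (log2 2.11 ± 0.27, adjusted p = 0.00112). In untreated and siamycin libraries AFUB_048310 was at 509 ± 30.2 and 462 ± 66.8, near its value with the combination. AFUB_036280 fell from 814 ± 325 to 174 ± 34.2 (log2 -2.14 ± 0.46, adjusted p = 0.0259) and AFUB_036270 from 580 ± 183 to 146 ± 50.0 (log2 -1.97 ± 0.30, adjusted p = 0.00194). Ribosomal RNAs did not pass the test here (18S log2 0.33, adjusted p = 0.471; 28S log2 0.14, adjusted p = 0.889), nor did U3 (log2 0.41, adjusted p = 0.118). The number of calls was sensitive to the method, with 24 with edgeR at a fold change above 1.5 and 954 with DESeq2. Single libraries also moved it: 149 without caspofungin replicate b or combination replicate c, 191 without combination replicate b and 251 without caspofungin replicate c. The AFUB_036280 call ended with limma-voom (adjusted p = 0.0534) and without caspofungin replicate b (0.0823) or c (0.0719), or combination replicate b (0.086) or c (0.0853).

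Of the 270 genes called for siamycin both with and without caspofungin, 64.1% moved in the same direction. Fold changes of siamycin versus untreated and combination versus caspofungin, which share no library, correlated across genes at 0.15 (jackknife SE 0.0506; Spearman 0.192); unchanged groups simulated 50 times gave a mean of -0.000153 and a highest of 0.025. Genes were again simulated independently, which keeps the simulated values near 0. Real deviations from the group means correlated at -0.365 to 0.269 between same-letter libraries of different groups. The simulation therefore does not show that 0.15 lies beyond chance. Random regroupings, which mix treatments as above, ranged from -0.909 to 0.952, and 34 of 100 were as high or higher. Of 270 genes called in both, 52 rose and 121 fell in both, against 38.9 and 65.7 for independent lists, and 97 moved in opposite directions against 114. Of the 458 genes at least 2-fold higher with siamycin than untreated, 10 rose and 32 fell when siamycin was added to caspofungin, with a median log2 change of 0.14. Of the 114 at least 2-fold lower, 1 rose and 9 fell, with a median of -0.14.

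Caspofungin and siamycin, compared directly at 4 h, differed in 4460 genes, 2137 higher and 2323 lower with caspofungin. At least 2-fold, 438 were higher and 1080 lower. AFUB_051200 was higher with caspofungin by 8.28 ± 0.17 on the log2 scale (SE, n = 3 each, adjusted p = 2.95e-15). AFUB_101920 was at 1429 ± 424 normalised reads with caspofungin and 3.15 ± 2.56 with siamycin (SD; log2 7.66 ± 0.26 SE, adjusted p = 1.09e-12). AFUB_087570 was at 36.8 ± 41.2 with caspofungin and 4302 ± 661 with siamycin (log2 -7.19 ± 0.50, adjusted p = 6.84e-07), and AFUB_084630 at 6.58 ± 2.43 and 1188 ± 236 (log2 -6.82 ± 0.25, adjusted p = 1.48e-12). U3 was higher with caspofungin by 1.48 ± 0.13 (adjusted p = 8.88e-08), RNase_MRP by 1.09 ± 0.20 (adjusted p = 0.000172) and U4 by 0.99 ± 0.25 (adjusted p = 0.00305). The RNase_MRP call ended at equal depth, at 0.99 (adjusted p = 0.162), and with library totals alone U4 was at 0.48 (adjusted p = 0.112). With library totals alone the median gene shifted by -0.64 and 6.72% of 6681 calls were higher with caspofungin, against 47.9% here; with upper-quartile factors 56.5% of 5097 were higher, which turned the majority.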

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

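The tests of the 3 patterns weighed in this part were chosen after the results had been seen. The change with caspofungin differed between cultures with and without siamycin for 1892 genes, 758 with a positive and 1134 with a negative difference, by limma's test of the difference itself. The majority turned with upper-quartile factors (1046 positive and 953 negative), and library totals alone gave 352 and 1086. Another grouping of the 12 libraries reached 1700 genes, the highest of the 99 others drawn, so that 1 of 100 groupings, the real one, gave as many. Such groupings mix libraries with and without caspofungin and are no reference for unchanged groups. Because untreated libraries were taken at 0 h, this difference also holds the 4 h of culture with a minus sign and is not an interaction.

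In AFUB_036280 the difference was -6.50 ± 0.57 SE (adjusted p = 3.5e-05): it rose by 6.06 with caspofungin alone and moved by -0.45 when caspofungin was added to siamycin. In AFUB_036270 it was -5.92 ± 0.37 (adjusted p = 6.8e-08), from 5.43 and -0.49. In AFUB_091070 it was 4.18 ± 0.43 (adjusted p = 7.08e-05), from -0.70 and 3.48. U3 had a difference of 1.62 ± 0.18 (adjusted p = 2.37e-05), from 0.27 and 1.89. AFUB_047540 had a fitted difference of 7.96, which depends on the pseudocount and is no bound, and edgeR did not call it under any of 7 settings (adjusted p = 1), while DESeq2 and limma-voom did. With siamycin and with the combination AFUB_047540 had 0 reads, so its change when caspofungin was added to siamycin was fixed at 0. Its fitted difference only restates its fall against untreated and shows no differing caspofungin effect. Of the 20 features named in any comparison, 6 others were called in this contrast.

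The first pattern weighed is the ribosomal RNA share of the libraries with caspofungin. General carry-over of RNA without poly(A) tails would raise other non-coding RNAs about as much. The median log2 change of SNORD14, U4, RNase_MRP and U3 was 0.36 with caspofungin, far below the rise of 18S. How far extraction and library preparation kept such small RNAs is not given, nor whether poly(A) RNA was selected. Their values therefore cannot decide on carry-over of long ribosomal RNA. A single factor from less mRNA per cell would lift 18S and 28S alike, yet the log2 of 28S over 18S was 2.41 higher with caspofungin than untreated. The 28S row was small, from 0.448% to 0.926% of the 18S reads in untreated libraries. The larger unnamed feature rose by 7.45 ± 0.20 SE and 18S by 6.26 ± 0.22. How much of each ribosomal RNA these rows cover is not given, so the ratio does not settle this explanation. A difference in library preparation that coincided with caspofungin cannot be told apart from the drug, because the labels give no preparation batch; that 0 of the 6 libraries with caspofungin lay under 5% restates the pattern and decides nothing. A biological origin in ribosomal RNA turnover was not tested either.

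The second is AFUB_047540, the 1 tag with a value of at least 35 in each untreated library and 0 reads in all 9 treated libraries. Tags below that value were not counted. Lower depth of the treated libraries is argued against: at the untreated level the treated library with the lowest expectation would hold 288 reads. A difference over a block of neighbouring tags is argued against by the 3 tested tags on each side, whose lowest siamycin change was -0.31. Switch-off in all 3 treatments would need half-lives of at most 26.7 min with caspofungin, 23.4 min with siamycin and 29.0 min with the combination to reach the floor of 3 reads over each group, and no other tag fell to a like extent: 2 others fell at least 4-fold in all 3 groups, and the stronger of them had -2.77 on the log2 scale as its weakest fall. Switch-off and a strain or counting difference at this tag alone (0 reads over the 9 treated libraries) cannot be told apart because treatment, time and the untreated cultures coincide.

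The third is the smaller number of calls for siamycin added to caspofungin. Lower depth may lessen calls, but at equal depth siamycin versus untreated still called 5.01 times as many genes with group weights (2660 against 531), 4.62 times without weights and 4.34 times with edgeR. At full depth the ratio varied with the method. It was 3.30 without weights, 4.15 with DESeq2, 5.85 with edgeR and TMM and 8.67 with the group weights, which were chosen after the data had been seen. Other settings lay further apart: 4024 against 405 calls with limma-voom, 4182 against 327 without a filter and 749 against 24 with edgeR at a fold change above 1.5. The 4 h of culture, which only the comparison with untreated holds, cannot be told apart from the drug: of genes called for both single compounds, 38.5% moved in opposite directions, and the rest could be moved by time. A lessened siamycin response in the presence of caspofungin is an untested hypothesis, since no untreated library at 4 h was analysed here.

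For the pairwise comparisons, the 10 splits of 6 libraries are too few for a share under 0.05. In each, 1 of the 10, the real one, reached the real count. The highest other split called 0 genes for caspofungin, siamycin and combination versus untreated (real 4217, 3911 and 4721) and for combination and caspofungin versus siamycin (4585 and 4460), and 1 gene for combination versus caspofungin (451). Each other split mixes both groups of its comparison, which widens the spread within its parts where the groups differ. Such splits are no reference for unchanged groups.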

How the results depend on the processing

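Settings chosen after seeing the data were edgeR with TMM, other pseudocounts and weights, equal depth (also without weights and with edgeR) and library totals without ribosomal RNA rows. Of 1420 values of 57 gene results under alternatives, 1332 kept direction and side of the threshold, 85 no longer passed and 3 reversed, all with library totals alone: RNase_MRP (-0.088 for caspofungin and -0.21 for combination versus untreated) and U3 (-0.20 for combination versus untreated). Ribosomal reads enter these totals. With them, calls were 7370 for caspofungin, 7612 for combination versus untreated, 7233 for combination versus siamycin and 923 for combination versus caspofungin (rises 8.45% against 31.9%); for the 1892-gene contrast rises were 24.5% against 40.1%, and 52.3% with upper-quartile factors. Library totals without ribosomal rows gave rises of 44.7% for siamycin versus untreated (55.8%) and 58.7% for caspofungin versus siamycin (47.9%).

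With edgeR and TMM, a fold change above 1.5 left 1609, 749 and 1571 calls for caspofungin, siamycin and combination versus untreated. It left 24 for combination versus caspofungin, and 1770 for combination and 1937 for caspofungin versus siamycin. For the contrast of 1892 genes it left 321 and for the overlap 173. This criterion asks for larger changes, and the test differs from limma as well. Without the criterion, edgeR with TMM gave 672 calls for combination versus caspofungin. Combination versus caspofungin (451) also moved to 737 with upper-quartile factors (rises 46.3%), 954 with DESeq2 (49.1%), 959 without weights (42.1%), 756 with library totals without ribosomal rows and 689 with the replicate block; DESeq2 size factors gave 639 (44.0% rises). The cause was not tested. Spearman's coefficient for the caspofungin effect was 0.708 against 0.81.

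Leaving out 1 library gave 3344 to 4415 calls for caspofungin, 2847 to 4048 for siamycin and 3883 to 4881 for combination versus untreated, 149 to 425 for combination versus caspofungin, 4048 to 4362 for combination and 3674 to 4450 for caspofungin versus siamycin. It gave 1475 to 2111 for the contrast of 1892, 777 (without untreated replicate c) to 1370 for the overlap, 0.802 to 0.813 for the caspofungin and 0.116 to 0.164 for the siamycin correlation. The labels do not say that the replicate letters pair the libraries, and 8 of 18 same-letter pairs had deviations correlated over 0.1 (-0.365 to 0.269), short of all; 8 of 12 libraries were closest to their own letter, a hint of pairing from the data. With the block, calls were 3800, 3941 and 4640 versus untreated, and 5203 and 4760 versus siamycin. The planned gene list tests were not run, since 0 identifiers matched. Of simulated 1.5-fold changes, 50.8% were recovered for combination versus caspofungin with group weights and 63.6% without; what depth alone limits there was not isolated.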

Other observations

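The test of runs was chosen after the pattern had been seen. With caspofungin, 26 consecutive tested tags from AFUB_085960 to AFUB_086220 all rose against untreated, with a median of 8.05-fold (log2 3.01, range 0.50 to 4.00). The same tags had a median of 2.94-fold with siamycin, where 24 rose and 1 fell, and 4.68-fold with the combination, where 25 rose. Adding siamycin to caspofungin lowered 18 of the 26 and raised 0, with a median log2 change of -0.69, and 25 were higher with caspofungin than with siamycin. The tags were picked as higher in the caspofungin than in the untreated libraries. All these comparisons reuse libraries of that pick, so the picking itself favours such directions. Combination versus siamycin shares no library with the pick. There 20 of the 26 rose, 0 fell and 6 were not called, with a median log2 change of 0.54. Over all tested features, 2151 of 8079 rose in that comparison. The mean log2 value over the run was 8.51 ± 0.00633 in untreated libraries, 11.2 ± 0.0959 with caspofungin, 9.85 ± 0.10 with siamycin and 10.6 ± 0.139 with the combination (SD, n = 3 each). The tags carry no names or coordinates in the sources used here, and consecutive numbers are assumed to mean neighbouring genes.

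A candidate explanation is that neighbouring genes in this stretch respond together. Shuffling the calls over the tags 10000 times gave a longest run of rises of at most 15 (median 6), against 26 observed (permutation p = 1e-04, the smallest these shuffles can give), and edgeR calls gave a run of 26 with the same first and last tag. Falls with siamycin showed no such excess, with a longest run of 6 (permutation p = 0.45), nor did falls with the combination versus untreated, with 9 (permutation p = 0.11). The other 10 of the 12 directions tested had longer runs than 95% of shuffles, so the pattern is a hypothesis found and tested on the same libraries, and duplicated genes that share reads would also lengthen runs.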
